A study of Mus musculus with 24 samples.

How the data were processed

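Total RNA from mouse brain was measured on 2 Affymetrix array designs, called array A and array B here. Per the labels, 6 samples of each array design were 2N and 6 were Ts1Cje, which gives 24 arrays. The labels name the tissue as brain and give neither brain region, age nor sex. They number the samples 1 to 6 within a genotype and do not say that the samples came from separate animals, so the p-values measure the spread between these samples, which may be partly technical. No column was left unmapped.

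The deposited values were intensities, 1 per probe set and array, on a linear scale. How the authors summarised the probes of a set, and with which software and scaling, is not given in the sources used here. The median deposited intensity ran from 11.2 to 21.7 on array A and from 7.9 to 13.8 on array B. The 2% trimmed means of the arrays differed by up to 2.10-fold on array A and 1.86-fold on array B. By a rule fixed before the data were examined, tables whose trimmed means differed by more than 5% were quantile normalised, so this was done for both. The number of arrays limits the precision of every value.

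After leaving out 66 control probe sets on each array, array A held 12422 probe sets and array B 12411. The platform annotation gave 1 gene symbol for 10833 of them on array A, several for 396 and none for 1193. On array B the numbers were 10581, 178 and 1652. Of the probe sets with 1 symbol, 10821 and 10561 matched a gene of the reference annotation (GRCm38.p6), and no symbol changed. That annotation was used only for names and gene order. Probe sets with several symbols were not given a name.

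Within each table, values below the 10th percentile of the table were set to it, which was 1.47 on array A and 1.13 on array B, and log2 was taken. Probe sets with a mean at or above the 25th percentile were tested, 9316 on array A and 9308 on array B. The test was limma (version 3.58.1 in R 4.3.3) with lmFit and eBayes with a mean-variance trend, for Ts1Cje against 2N with no other term. A probe set passed with a Benjamini-Hochberg adjusted p under 0.05 within its table. The tables were normalised separately and tested apart. A gene was represented by its brightest probe set naming it alone. In counts over both arrays the array A probe set was used where a gene was on both. Folds are ratios on the log2 scale after the floor, which can shrink the change of dim genes. Errors of intensities are SD over 6 samples, and those of log2 differences are standard errors of the limma fit with 95% intervals.

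The 29 gene lists were fixed before the data were examined. They hold 68 genes of the trisomic segment, Sod1 as its boundary, orthologs of human chromosome 21 genes that are disomic in Ts1Cje (on mouse chromosome 16 and on chromosomes 17 and 10), genes of distal chromosome 12, markers of 13 cell types or tissues, 10 pathways or gene classes, and sex-linked genes. The mean log2 value of each list was compared between genotypes by a two-sided exact permutation test over all 924 splits of the 12 samples. Lists with at least 5 measured genes were also tested with limma camera with a preset correlation of 0.01, adjusted over the lists of the table, beside camera with an estimated correlation and fry.

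Genes were named by a rule fixed in advance. It took the segment genes that passed (up to 15) and 5 bright ones that did not, Sod1 and App. When none outside the segment passed, it took the 3 with the smallest p on each array among probe sets given a name. It also took up to 4 members of each list, those that passed or else the 2 brightest, and every measured gene of distal chromosome 12. Genes outside this rule are said to have been chosen after their values were seen.

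The pipeline was tested on simulated data with the means and spreads of the real tables. Noise was drawn independently for each value, so correlation between genes was absent. More probe sets were changed than passed in the real tables, which eases the adjustment. The shares and false calls below therefore need not hold for the real tables. On array A it recovered 39.4% of 94 probe sets changed 1.5-fold and 65.6% of 96 changed 2-fold, with 6 false calls among 9316 probe sets. For probe sets above the median intensity the shares were 65.3% and 91.7%. On array B it recovered 26.5% of 98 and 59.2% of 98, with 5 false calls among 9308. Of the brighter probe sets there, 51.0% and 84.5% were recovered. The alternatives tried changed the normalisation, floor, offset, filter, test, array weights, replicate block, gene summary, threshold, segment list and camera correlation, and left out each sample in turn.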

Results

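Gene expression was compared between the brains of Ts1Cje mice and 2N mice, which have the normal chromosome complement. Ts1Cje mice are a model of Down syndrome. They carry an extra copy of a distal part of mouse chromosome 16 that holds many orthologs of human chromosome 21 genes, translocated onto distal chromosome 12. The extra copy begins next to Sod1, and Sod1 itself was disrupted on it. Each genotype had 6 samples on array A and 6 on array B. The sample titles carry the same numbers on both arrays, without stating whether a number stands for the same RNA. Tests that combined the arrays matched them by number. Agreement between the arrays therefore need not be independent replication. Spearman correlations between arrays lay between 0.914 and 0.957 on array A and between 0.884 and 0.926 on array B, and no arrays held identical values. The actin 3' to 5' signal ratio, a measure of RNA integrity, was 1.18 ± 0.138 (SD, n = 6) in 2N and 1.18 ± 0.0660 (SD, n = 6) in Ts1Cje on array A (exact permutation p = 0.99), and 1.32 ± 0.103 against 1.28 ± 0.0956 on array B (exact permutation p = 0.51). Xist, the RNA of the inactive X chromosome, differed by -0.10 (SE 0.092, limma adjusted p = 0.99).

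Genes of the trisomic segment were higher in Ts1Cje brain. Averaged over the 31 segment genes measured on array A, the log2 difference was 0.51 (SE 0.052), or 1.43-fold, and over 26 genes on array B it was 0.48 (SE 0.050), or 1.39-fold. On both arrays 6 of 6 Ts1Cje samples lay above all 2N samples, and the two-sided exact permutation p was 0.0022, the smallest that 924 splits can give. Adjusted over all 29 lists of array A this p was 0.063, and over the 23 lists of array B it was 0.025. A lone list at the smallest possible p cannot fall below 0.063 with 29 lists. On array B the oxidative stress response list tied with the segment at that p, which lowered the adjusted value. The 2 adjusted values therefore do not set the arrays apart. Disomic orthologs of human chromosome 21 genes elsewhere on chromosome 16 differed by -0.13 on array A (SE 0.10, exact permutation p = 0.23) and -0.02 on array B (SE 0.062, p = 0.79). The array A value was -0.05 without 2N replicate 1 and -0.03 with the 50th percentile filter, and the array B value was -0.09 without a filter (exact permutation p = 0.045). On array B it was just above 0 without 2N replicate 1 or Ts1Cje replicate 4, and 0.05 without normalisation between arrays. Orthologs on chromosomes 17 and 10 differed by 0.03 (SE 0.044, exact permutation p = 0.50) and -0.00447 (SE 0.068, p = 0.94). Replicates 1 and 2 of both genotypes stood apart from replicates 3 to 6 on both arrays, a split found only in the data. The segment difference among replicates 3 to 6 was 0.57 on array A and 0.49 on array B (exact permutation p = 0.029 for each, the smallest possible). Among replicates 1 and 2 it was 0.40 and 0.45, where the smallest possible exact p is 0.33. With 64 added to each value before log2, which shrinks differences of dim genes, the difference was 0.21 on array A and 0.18 on array B (exact permutation p = 0.0022 for each). Without normalisation between arrays the array A difference was 0.46 and did not pass (exact permutation p = 0.067).

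**Figure D1:**
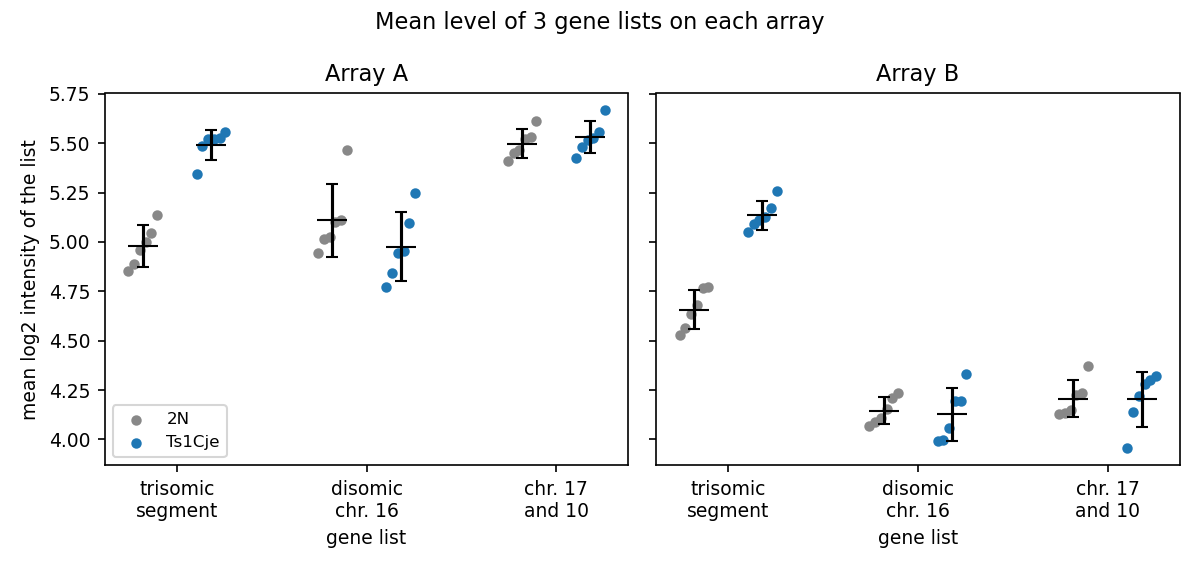
Mean log2 intensity of 3 gene lists (horizontal axis) on each array, for 2N (grey) and Ts1Cje (blue) samples; points are samples, bars the mean and SD of 6. For the trisomic segment 6 of 6 Ts1Cje samples lie above all 2N samples on both arrays, and for the other lists the genotypes overlap.

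The segment list is partial, since the reference annotation holds 166 genes distal to Sod1. Of the 68 listed segment genes 51 were measured, and 12 of them passed the threshold, all higher in Ts1Cje (limma). Adjusted over the list alone, 28 passed. The log2 difference was above 0 for 49 genes and below 0 for Kcnj6 and Bace2, the 2 genes chosen here after their values were seen. The median was 0.51, or 1.43-fold. The 95% interval held the 1.5-fold ratio of 3 copies to 2 for 44 genes. It lay above that ratio for Son and below it for 6. The interval excluded 0 for 29 of the 51 genes, so some of the 44 are wide enough to hold both 0 and 1.5-fold. All 9 probe sets that passed on array A and all 6 on array B belonged to the segment. One of those on array A is annotated to a pair of neighbouring segment genes, so it is counted but not named.

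**Figure D2:**
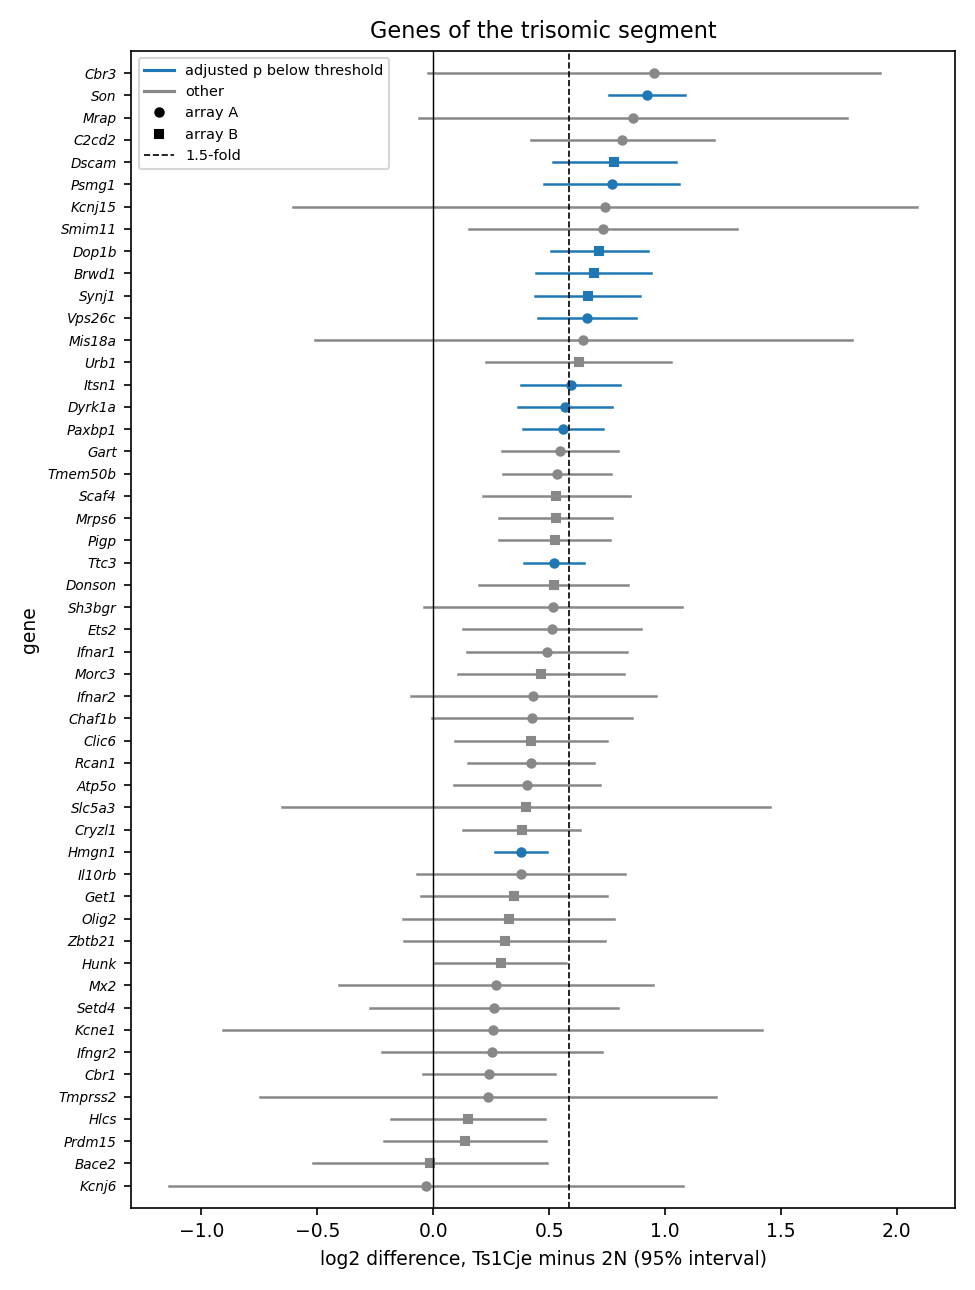
Log2 difference between Ts1Cje and 2N (horizontal axis) with its 95% interval for the 51 measured segment genes (vertical axis); blue marks the 12 genes past the threshold, circles array A and squares array B. The dashed line is 1.5-fold, which 44 of the intervals hold, and 29 of the 51 intervals exclude 0.

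Son, which encodes an RNA splicing cofactor, had the smallest p. Its intensity was 127 ± 8.59 in 2N and 242 ± 20.6 in Ts1Cje (SD, n = 6), a log2 difference of 0.92 (SE 0.079, limma adjusted p = 1.03e-05). Its probe set on array B also rose, by 0.79 (adjusted p = 0.016), but lost its call in 6 of 12 fits with a sample left out (2N replicate 5 and Ts1Cje replicates 1, 2, 3, 5 and 6). A dimmer Son probe set on array A differed by 0.66 (adjusted p = 0.92) and did not pass. Ttc3, a ubiquitin ligase gene, rose from 509 ± 35.8 to 729 ± 34.7 (log2 difference 0.52, adjusted p = 0.00065). Hmgn1, which encodes a nucleosome-binding protein, rose from 1098 ± 61.5 to 1426 ± 65.3 (0.38, SE 0.054, adjusted p = 0.0054), and its interval of 0.26 to 0.49 lay below 1.5-fold. Dyrk1a, a protein kinase gene, rose by 0.57 (SE 0.097, adjusted p = 0.020). Among genes of synapses and membrane traffic, Synj1, which encodes the phosphatase synaptojanin 1, rose by 0.67 and the endocytic scaffold gene Itsn1 by 0.59. The retromer-related Vps26c rose by 0.66 and Dop1b by 0.72. Dscam, a neuronal cell adhesion gene, rose by 0.78, Brwd1 by 0.69, Paxbp1 by 0.56 and the proteasome assembly gene Psmg1 by 0.77. Ifngr2, which encodes a chain of the interferon gamma receptor, differed between arrays, with 0.76 on array B, which passed (adjusted p = 0.016), and 0.26 on array A, which did not (adjusted p = 0.99). Itsn1 did not pass on array B, where 3 probe sets were at 0.33, 0.49 and 0.39. Further probe sets of genes that passed did not pass themselves. They were at 0.27 for Dyrk1a (SE 0.21, adjusted p = 0.99), 0.40 for Vps26c (SE 0.11, adjusted p = 0.62), 0.64 and 0.42 for Synj1 (adjusted p = 0.12 and 0.996) and 0.62 for Brwd1 (adjusted p = 0.93).

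Among the brightest segment genes that did not pass, Tmem50b differed by 0.53 (SE 0.11, limma adjusted p = 0.12) and the purine synthesis gene Gart by 0.55 (SE 0.12, adjusted p = 0.18). The calcineurin regulator Rcan1 differed by 0.42 (SE 0.13), the mitochondrial ATP synthase gene Atp5o by 0.41 (SE 0.15) and the carbonyl reductase gene Cbr1 by 0.24 (SE 0.14), each with an adjusted p of 0.99. The interval of Cbr1 ended at 0.53, below 1.5-fold. The number of segment genes past the threshold was 12, but 7 without 2N replicate 5 or without Ts1Cje replicate 1. Without 1 sample in turn, Psmg1 lost its call in 9 of 12 cases, Dyrk1a in 8, Brwd1 in 7, Itsn1 in 6, Dscam in 4, and Ifngr2 and Synj1 in 3 each, with adjusted p no higher than 0.104. Tmem50b passed without Ts1Cje replicate 6 (adjusted p = 0.035). The number of segment genes was 1 without the mean-variance trend, 6 with the plain test and 0 without normalisation between arrays.

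In gene order along chromosome 16, genes were divided at Sod1, and the differences were higher on the distal side of Sod1. Of 54 measured genes distal to it, 50 were above 0, with a median of 0.48, and 12 passed. Of 320 on its centromeric side, 143 were above 0, with a median of -0.02, and 0 passed. Only 1 of the 10 measured genes nearest to Sod1 on that side lay above the median intensity, so the exact point of change is not resolved.

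**Figure D3:**
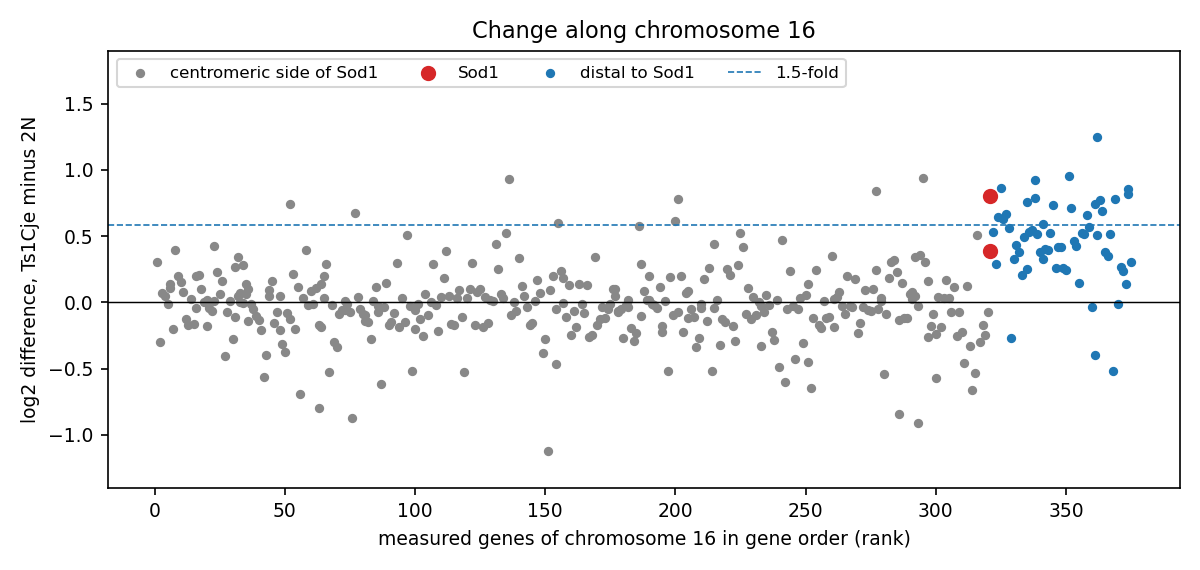
Log2 difference between Ts1Cje and 2N (vertical axis) for measured genes of chromosome 16 by rank in gene order (horizontal axis); a gene on both arrays has a point for each. Distal to Sod1, 50 of 54 genes lie above 0, counted with 1 probe set per gene, against 143 of 320 on the centromeric side.

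Sod1, which encodes copper-zinc superoxide dismutase, was at 184 ± 34.7 in 2N and 241 ± 40.9 in Ts1Cje on array A (SD, n = 6). Its log2 difference of 0.39 (SE 0.12) did not pass over all probe sets (limma adjusted p = 0.99), and its exact permutation p alone was 0.024. On array B the Sod1 probe set was dim, at 7.69 ± 2.72 and 12.8 ± 1.81, with a difference of 0.80 (SE 0.26, adjusted p = 0.996) and an exact permutation p of 0.0043. Adjusted over the lists of each table, these exact p-values were 0.23 and 0.033. Among replicates 3 to 6 the differences were 0.37 and 0.75, and among replicates 1 and 2 they were 0.44 and 0.92. App, the amyloid precursor protein gene, which is disomic in Ts1Cje, was at 1839 ± 209 and 1882 ± 117 (0.04, SE 0.071, adjusted p = 0.99).

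Outside the listed segment genes 0 of 9278 probe sets passed on array A and 0 of 9273 on array B (limma). Unlisted genes distal to Sod1 are counted as outside here. An unadjusted p under 0.05 was reached by 318 and 372, where 463.9 and 463.65 would be reached by chance. Why both counts fell below chance was not tested, and 0 calls do not show that no gene outside the segment changed. The plain test per probe set gave 2 outside calls, Zfp467 and Socs2, both chosen here after their values were seen. The smallest adjusted p was that of Mt1, a metallothionein gene, on array A. Mt1 was at 148 ± 8.09 in 2N and 204 ± 28.0 in Ts1Cje (0.45, SE 0.093, adjusted p = 0.12), and it passed without Ts1Cje replicate 4 (adjusted p = 0.013). Its array B probe set, at a mean intensity of 53.1, differed by 0.05 (SE 0.12, adjusted p = 0.996). The nucleolar gene Fbl differed by -0.47 (SE 0.10, adjusted p = 0.19) and the kinase gene Mark1, near the floor in Ts1Cje, by -2.39 (SE 0.57, adjusted p = 0.35). The brighter Mark1 probe set on array B, at 163.6, differed by 0.0062 (SE 0.086). On array B the smallest limma p-values among probe sets given a name were those of the inositol phosphate kinase gene Ip6k2, Rabggta and Peak1. Ip6k2 differed by -0.58 (SE 0.13, adjusted p = 0.31) and Rabggta by -0.54 (SE 0.14, adjusted p = 0.73). Peak1 differed by -1.54 (SE 0.40, adjusted p = 0.73). The Rabggta probe set on array A was at 0.03. None of the 6 genes named by the rule passed, but Fbl passed without Ts1Cje replicate 3 (adjusted p = 0.024) and Ip6k2 without Ts1Cje replicate 6 (adjusted p = 0.041).

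The oxidative stress response list stood above other genes in Ts1Cje on both arrays with the preset correlation, but not with an estimated one (adjusted p = 0.11 on array A and 0.051 on array B), and 0 of its 20 measured genes passed. On array A its mean difference was 0.12 (SE 0.035, exact permutation p = 0.013, 0.19 adjusted over the lists) and its camera adjusted p was 0.031. Without Sod1 the camera adjusted p was 0.091, a choice made after the data were seen. Adjusted over the list alone, 3 members passed, namely Mt1, Sod1 and Mt2, another metallothionein gene, chosen here after its value was seen, at 0.33. The brightest members, the peroxiredoxin gene Prdx2 and the thioredoxin gene Txn1, differed by 0.03 and -0.04. On array B 5 probe sets, dim except that of Mt1, had a mean difference of 0.47 (SE 0.090, exact permutation p = 0.0022) and a camera adjusted p of 0.0089, which was 0.083 without a filter.

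Pituitary markers were higher on array A with the preset correlation (6 measured, 0 passed, mean difference 0.47, camera adjusted p = 0.031), and the adjusted p was 0.31 with an estimated correlation. The exact permutation p of their mean was 0.045, or 0.33 adjusted over the lists. Their brightest members, the hormone genes Lhb and Gh, differed by 0.17 (SE 0.19) and 0.23 (SE 0.18). Even these were near the median intensity of 30.8 of the tested probe sets, at 38.0 and 28.7 in 2N, so the list is dim. The median difference of its members was 0.29. Cell cycle genes were lower on array A (25 measured there, 0 passed, camera adjusted p = 0.031), with an adjusted p of 0.31 with an estimated correlation. The mean difference was -0.16 (SE 0.10, exact permutation p = 0.15, 0.65 adjusted over the lists). The replication genes Mcm5 and Mcm7 differed by -0.19 (SE 0.097) and -0.07 (SE 0.11). On array B only 2 cell cycle genes were measured, with a mean difference of 0.47 in the other direction. With a sample left out, the call was lost in 5 of 12 cases for the oxidative stress list on array A, 6 for pituitary markers and 6 for cell cycle genes. With an estimated correlation the trisomic segment was the one list called on either array (adjusted p = 7.86e-07 and 7.84e-06). By fry the segment was called on array A, and the segment and the oxidative stress list on array B (adjusted p = 0.0023 for the latter). In fry's test for change in either direction, calcineurin-NFAT signalling was also called on array A (adjusted p = 2.95e-05), a list that holds the segment genes Dyrk1a and Rcan1.

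Markers of brain cell types did not pass camera on array A, nor did the neuronal, glutamatergic, astrocyte and oligodendrocyte lists on array B, where the others were too small to test. Of their measured genes 0 passed. The mean difference on array A was 0.07 for neuronal markers (SE 0.035, exact permutation p = 0.074), -0.03 for GABAergic markers (SE 0.048), 0.02 for glutamatergic markers (SE 0.075) and 0.06 for astrocyte markers (SE 0.069). It was -0.05 for oligodendrocyte and myelin markers (SE 0.12), -0.09 for microglia markers (SE 0.082), 0.10 for endothelial markers (SE 0.095) and -0.08 for neural progenitor markers (SE 0.079). Tubb3, a neuronal tubulin gene, differed by 0.07 and Stmn2 by 0.05. Among interneuron genes, Sst and Slc32a1 differed by 0.10 and -0.04. The glutamate receptor gene Gria2 differed by 0.13 and the cortical transcription factor gene Tbr1 by -0.05. Fabp7 and Apoe differed by 0.00222 and -0.00286, Pdgfra and Sox10 by -0.01 and -0.06 (on array B Sox10 differed by 0.46, SE 0.13, adjusted p = 0.92), C1qc and C1qa by -0.32 and 0.03, Cldn5 and Eng by 0.05 and 0.27, and Sox2 and Nes by 0.08 and 0.04. On array B the mean difference had the other sign for neuronal markers at -0.04, oligodendrocyte and myelin markers at 0.18 (exact permutation p = 0.20) and endothelial markers at -0.29 (p = 0.12). The oligodendrocyte and myelin list there holds 1 segment gene, at 0.33, and without that gene it is too small for camera. Over all lists measured on both arrays, the signs were opposite in 9 of 23.

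Markers of tissues next to the brain were compared in the same way on array A. Choroid plexus markers, with 4 genes too few for camera, differed by 0.23 (SE 0.16, exact permutation p = 0.17), with Igf2 at -0.13 and Ttr at 0.06. Meningeal and fibroblast markers differed by -0.03 (SE 0.083), with Ptgds at -0.06 and Igfbp2 at 0.04. Erythroid and blood markers differed by -0.17 (SE 0.17), with the haemoglobin genes Hba-a1 at -0.15 and Hbb-b2 at -0.17. Skeletal muscle markers differed by 0.28 (SE 0.20), with Tnnc2 at 0.78 and Acta1 at -0.02. None of these lists passed camera where it was run.

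The other pathways did not pass camera on array A, nor did calcineurin-NFAT signalling, oxidative phosphorylation and cholesterol biosynthesis on array B, where the others were too small to test. On array A the mean difference was -0.07 for the interferon response (SE 0.065), with H2-D1 at 0.02 and Ifitm3 at -0.26. It was 0.01 for Sonic hedgehog signalling (SE 0.16), with Mycn at 0.06 and Ccnd1 at 0.11, and 0.07 for calcineurin-NFAT signalling (SE 0.084), where the segment gene Dyrk1a passed and Ppp3r1 differed by 0.05. Immediate early genes differed by -0.11 (SE 0.11), with Btg2 at 0.05 and Dusp1 at -0.31. Oxidative phosphorylation genes differed by -0.03 (SE 0.035), with Cox6a1 at 0.00434 and Atp5l at 0.00966. Heat shock and unfolded protein response genes differed by 0.01 (SE 0.032), with Hsp90aa1 at 0.10 and Dnaja1 at -0.05. Cholesterol biosynthesis genes differed by -0.03 (SE 0.071), with Fdps at -0.04 and Fdft1 at -0.18. Cytosolic ribosomal protein genes differed by -0.02 (SE 0.050), with Rpl41 at 0.07 and Rps28 at -0.00997. On array B, lists too small for camera, other than that of Sod1 alone, with an exact permutation p under 0.05 were Sonic hedgehog signalling at -0.28 (3 genes, p = 0.032), cell cycle genes (p = 0.032) and the single choroid plexus gene measured, at 0.42 (p = 0.019), which lies in the segment. Adjusted over the lists these were 0.12, 0.12 and 0.11. The disomic orthologs Atp5j, Sumo3 and Pdxk differed by -0.09, 0.03 and -0.00746. The median, mean and camera direction differed in sign for the interferon, glutamatergic, heat shock, ribosomal and chromosome 17 and 10 lists on array A, and for both disomic ortholog lists on array B.

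Distal chromosome 12, which the segment is joined to in Ts1Cje, had 3 measured genes, and 0 passed. Cdca7l differed by 0.74 (SE 0.42, limma adjusted p = 0.99) and Sp4 by -0.38 on array A (SE 0.23, adjusted p = 0.99) and -0.46 on array B (SE 0.19, adjusted p = 0.996). Rapgef5 differed by 0.10 (SE 0.11). The list mean differed by 0.18 on array A (exact permutation p = 0.63) and by -0.18 on array B (p = 0.093). The array A mean was -0.036 without 2N replicate 2. The array B mean passed with all probe sets of a gene averaged (-0.27, exact permutation p = 0.039), without 2N replicate 4 (p = 0.028) and without Ts1Cje replicate 1 (p = 0.048).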

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

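In 24 of 250 groups of 6 samples, 1 sample lay far from the other 5, by a limit that chance exceeds in about 1 in 20 groups. The values are normalised intensities, or mean log2 intensities for lists, and on array A unless stated.

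Among segment genes, Dyrk1a was at 82.8 in 2N replicate 5, against 66.3 to 70.8 in the other 2N samples. In Ts1Cje replicate 6, Psmg1 was high at 123.7 (others 68.4 to 85.4), while Tmem50b was low at 222.8 (others 283.3 to 319.5) and Rcan1 low at 114.4 (others 155.6 to 183.4). Within the Ts1Cje group the segment mean was low in replicate 2, at 5.34 (others 5.48 to 5.56), and still above every 2N sample.

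Elsewhere, 2N replicate 1 was low for Tubb3 at 2342 and Ifitm3 at 33.8, and high for Eng at 129.1. In 2N replicate 2, Tnnc2 was at 1.52, Cdca7l at 2.27, Cox6a1 at 958 and Rps28 at 2737, each the lowest of its group. Ptgds was at 654.8 in 2N replicate 3. Mark1 was at 2.37 in 2N replicate 5 and at 4.64 in Ts1Cje replicate 6, where the other Ts1Cje samples were at 1.47 to 1.5, close to the floor.

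Among list means, the disomic chromosome 16 orthologs stood at 5.46 in 2N replicate 1, and distal chromosome 12 at 2.56 and cytosolic ribosomal proteins at 8.99 in 2N replicate 2. Ts1Cje replicate 6 was low for erythroid and blood markers at 4.22 and pituitary markers at 3.01. The interferon response was at 3.85 in 2N replicate 6 and 4.20 in Ts1Cje replicate 4. Sonic hedgehog signalling was at 3.45 in Ts1Cje replicate 2. On array B neuronal markers were at 7.90 in 2N replicate 1.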

How the results depend on the processing

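The batch term for replicates 1 and 2 and the list without Sod1 were chosen after the data were seen. The segment mean kept its direction under every alternative run, but with 64 added before log2 it was 0.21 on array A and 0.18 on array B. Without normalisation between arrays it was 0.46 on array A and did not pass (exact permutation p = 0.067), and 0 probe sets passed on array A, 0 on array B and 0 segment genes. Without the mean-variance trend 2 passed on array A, 0 on array B and 1 segment gene, and 1 outside, Zfp467. With the plain test 9 passed on array A, of which 7 were those of the moderated test, 0 on array B, 6 segment genes and 2 outside. Without a filter 2 passed on array B. The cause of these changes was not tested. Trimmed-mean scaling, other floors, the offset, the stricter filter, the 0.10 threshold and the batch term kept all 9 and all 6 probe sets.

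The replicate numbers showed no clear pairing of the samples, but a weak pairing is not ruled out. The deviations of same-numbered samples, not their intensities, correlated by 0.017 to 0.077 on array A and by 0.013 to 0.11 on array B. Of these pairs 0 and 1 exceeded the threshold of 0.1, and 3 of 6 and 2 of 6 correlated best with their own number. With the replicate block 9 and 6 probe sets passed, sharing 9 and 4 with the fit without it. On array B Son and Synj1 lost their calls, and Pigp, chosen here after its value was seen, and 1 gene outside the segment, Ip6k2, gained them.

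Leaving out 1 sample gave 6 to 11 probe sets on array A, 1 to 6 on array B and 7 to 14 segment genes (7 without 2N replicate 5 or Ts1Cje replicate 1). The segment mean ran from 0.49 to 0.54 on array A and from 0.45 to 0.50 on array B. Array B fell to 1 without 2N replicate 5, Ts1Cje replicate 1 or Ts1Cje replicate 2. Outside the segment it gave 0 to 1, with Fbl without Ts1Cje replicate 3, Mt1 without replicate 4 and Ip6k2 without replicate 6.

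With an estimated correlation 1 list passed on array A and 1 on array B. On array A 2 passed without normalisation, and 1 to 4 with a sample left out (1 without 2N replicate 6, Ts1Cje replicate 1 or Ts1Cje replicate 5, and 2 without 2N replicate 1). On array B 1 passed without a filter and 1 with the 50th percentile filter. The oxidative stress list without Sod1 did not pass on array A (adjusted p = 0.091). The distal chromosome 12 mean was -0.27 on array B with all probe sets averaged and -0.18 with the batch term (exact permutation p = 0.033), and ran from -0.036 (without 2N replicate 2) to 0.26 on array A and from -0.24 to -0.14 on array B with a sample left out. For named genes that passed, 234 of 312 values stayed past the threshold and 0 changed direction. For the 67 named probe sets that did not pass, 95 of 1603 values changed direction and 6 passed. Tests without a trend or with the plain statistic do not apply to list means. Signal over background limits the dim probe sets.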

Other observations

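Several tests here were chosen only after the result was seen: those of measurement error, brightness (over all and over the brighter genes), probe sets, position, the neighbours of Sod1, Sod1 itself, the oxidative stress list without Sod1 and RNA degradation.

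With segment genes left out, no chromosome was called as shifted as a whole, chromosome 16 included. The smallest adjusted camera p over 20 chromosomes on both arrays was 0.92, and the largest median in size was -0.04. The 10 measured genes nearest to Sod1 on the centromeric side had a mean difference of -0.21 (95% interval -0.58 to 0.15, exact permutation p = 0.22), but only 1 of the 10 lay above the median intensity of the tested probe sets, so a spread of the rise past the boundary stays open. Along the segment, the size of the rise had a Spearman rho of -0.17 with gene order across 51 genes (permutation p = 0.23, 95% interval -0.46 to 0.13), which leaves a trend with position open. Genes are not independent replicates.

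Whether the oxidative stress list on array B rests on Sod1 alone stays open. Without it the mean difference was 0.39 (exact permutation p = 0.037), but only 1 of the 4 remaining probe sets lay above the median intensity. On array A the list did not pass without Sod1 (camera adjusted p = 0.091). Prdx2, at 7.25 on array B, contributed the most at 1.04 (SE 0.55), while its far brighter probe set on array A was at 0.03.

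Other splits of the 12 samples were drawn, 100 of the 462 possible with the real one included. The 9 probe sets on array A, 6 on array B and 12 segment genes were each reached by 1 of 100 splits, the real one, and the highest other counts were 1, 1 and 0, so chance can be excluded. For the 0 outside calls the comparison decides nothing, since each of 100 splits must give 0 or more; 9 of the other splits gave any, at most 1 each. The 4 lists on array A were reached by 1 of 100, with 3 the highest other, but the segment itself is 1 of the 4. With segment genes left out 3 lists passed there, no more than that highest other count. The comparison therefore does not exclude chance for these 3 lists. The 2 lists on array B were reached by 12 of 100, so chance cannot be excluded there.

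The size of the difference varied between segment genes. Measurement error alone was excluded over all by Cochran's Q of 90.8 over 51 genes (permutation of residuals, p = 0.00866), but this rested on Son: without it the permutation p was 0.16, so measurement error stays open for the other genes. Compression of bright probe sets stays open: rho with intensity across genes was 0.24 over all (permutation p = 0.085, 0.25 adjusted over 3 trends) and 0.15 over the 25 brighter genes (p = 0.46), and both 95% intervals (from -0.05 and -0.26) reached below 0. Differences between probe sets of 1 gene stay open, with a ratio of mean squares of 1.44 (permutation p = 0.21) over 16 genes. The 3 Son probe sets differed by 0.92, 0.66 and 0.79, and only the interval of the first lay above 1.5-fold, so a rise of Son beyond its copy number rests on 1 probe set.

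Sod1 was higher on both arrays without passing the adjustment over all probe sets. The difference was not due to replicates 1 and 2 alone, since among replicates 3 to 6 on array A it was 0.37 with no overlap between genotypes. Cross-hybridization stays open: the array B probe set differed the same way (exact permutation p = 0.0043), but at an intensity of 10.2 it lay below the median of 16.1 of the tested probe sets. A transcript from the disrupted extra copy that still reaches the probes may contribute, which was not tested.

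Replicates 1 and 2 of both genotypes stood apart from 3 to 6. With genotype in the model, 215 probe sets on array A and 148 on array B differed between these sets, against at most 7 and 1 for the other 14 pairs of numbers. The actin 3' to 5' ratio was higher in replicates 1 and 2 on both arrays (exact permutation p = 0.014 for each). The Gapdh 3' to 5' ratio, which was not tested, overlapped between the sets. In replicates 1 and 2 it ran from 0.959 to 1.11 on array A and from 1.03 to 1.17 on array B. In replicates 3 to 6 it ran from 0.960 to 1.19 and from 1.03 to 1.36. The 2 ratios differ in this, so whether RNA degradation contributed stays open. The deposited 18S rRNA signal was 233 ± 97.2 in replicates 1 and 2 against 128 ± 38.8 in 3 to 6 on array A (SD, n = 4 and 8). On array B it was 264 ± 82.9 against 91.8 ± 18.5. Deposited trimmed means on array B ran from 22.9 to 29.0 in replicates 1 and 2 and from 15.6 to 20.5 in 3 to 6, while those on array A overlapped. Hybridization or scanning stays open as well. The difference correlated by 0.068 between arrays across 564 genes. For the other pairs of numbers this correlation ran from -0.080 to 0.147, so it does not decide the question. Of 66 changed genes measured on both arrays, 40 went the same way (exact binomial p = 0.11). The split is balanced over genotypes, and no biological explanation was tested.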
